A study of Homo sapiens with 2 samples.

How the data were processed

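Gene expression was measured by RNA sequencing in PC3, a human prostate cancer cell line grown in culture. There were 2 libraries: 1 from cells transfected with a control small interfering RNA (siRNA) and 1 from cells transfected with an siRNA against POH1. POH1 is the deubiquitinase of the proteasome's regulatory particle, and its gene symbol is PSMD14. Each group held 1 library, so there was no replicate error, and no p-value, standard error or test between groups was computed. Every difference below is a difference between these 2 libraries, with no replicate check.

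Per the labels' protocols, RNA was taken with Trizol and libraries were made with an mRNA sequencing kit for Illumina instruments. Per the submitters' processing notes, CASAVA and HISAT2 were used and the genome build was hg19; versions, the gene annotation, the tool that produced the expression values, the use of strand and the read depth are not given in the sources used here. The deposited values are TPM per gene, a transcript abundance in which reads are divided by transcript length and scaled to a fixed total per library. The columns summed to 999955 TPM in the control library and 999968 TPM in the POH1 siRNA library. TPM keeps no read depth, so the depth is unknown, and no counting interval or detection limit is given. TPM is relative, so a change in a few very abundant transcripts shifts all others.

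The table listed 58174 Ensembl gene identifiers without symbols, and 57392 of them were given a symbol by identifier from a name table. Of all identifiers, 57836 are in GENCODE release 29, which annotates GRCh38 and not hg19, so no coordinates are printed. GENCODE release 29 was used for gene types, for the GC content of each gene (the median over its annotated transcripts) and for which genes share exon sequence. A GC content was found for 99.8% of the genes with a mean of 1 TPM or more. Where strand is not known to have been used, reads of genes that overlap on opposite strands cannot be told apart. This limit is repeated below for some genes only. It also holds for others, such as HSP90AA1, DDIT3, CDC25C, USP14 and RPS27A. Sharing of same-strand exons is likewise not named for every gene, such as HSPE1.

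The difference of a gene was computed as log2 of (TPM + 1) in the POH1 siRNA library less log2 of (TPM + 1) in the control library, over the 15008 genes with a mean of 1 TPM or more over both libraries. The pseudocount of 1 makes this difference smaller than the fold of the TPM values for low genes. Folds are ratios of the deposited TPM values. A gene was counted as higher or lower when its log2 difference reached a size of 1, and list members were counted at 1.5-fold on the same scale.

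The following were fixed before the data were examined: the 32 gene lists, the filters, the pseudocount, the alternatives not named below as added, and the rule for named genes. That rule named PSMD14, the 12 genes with the highest and the 12 with the lowest log2 difference among genes with a mean of 5 TPM or more and a gene symbol that was not a clone, pseudogene or small RNA name, and the 4 members of each list with the largest difference; regulators such as NFE2L1, ATF4, E2F1, CDKN1A and BCL2L11 could be given whatever their size. Some genes that the rule names are not reported here. Genes named outside this rule are said to have been chosen after their values were seen. Of the lists, 28 had at least 5 members with a mean of 1 TPM or more. For these, the median log2 difference was placed among the medians of 10000 random lists of the same size, drawn with replacement from genes in the same decile of mean TPM. A list was said to stand apart when its percentile was under 2.5 or over 97.5, which is a description of these 2 libraries and not a test between conditions. With 28 lists, 1.4 would stand apart by chance if genes varied independently. Members of a list are often regulated together, so the chance number is higher.

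Some settings were added after the data were seen. In one, random lists were matched on 5 classes of mean TPM and 10 classes of GC content, and for comparison on the 5 classes of mean TPM alone. In another, the running median of the log2 difference over 501 genes of at least 5 TPM, ordered by GC content, was subtracted from each gene and the overall median added back. Counts were also made over protein-coding genes, and without the genes that share same-strand exon sequence with another gene of at least 1 TPM. The alternatives fixed in advance were pseudocounts of 0.1 and 5, no filter and a filter at 5 TPM, scaling to a median log2 ratio of 0, scaling by a trimmed mean of log2 ratios, TPM recomputed without mitochondrial genes and the 50 most abundant genes, and random lists matched in 20 classes of mean TPM.

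The calculations were checked on simulated data. These held 14983 genes at the observed mean TPM, with 200 genes changed and noise with an SD of 0.2 on the log2 scale. This noise was set below the SD of the observed log2 differences (0.52), so the shares of unchanged genes counted are not error rates for these libraries. The rule found 100% of the 4-fold rises and 74% of the 4-fold falls, since a fall takes a low gene close to the pseudocount, and none of the unchanged genes. With a GC trend added to the simulation, it found 98% of the rises and 76% of the falls (82% after GC adjustment), and counted 9% of the 1.5-fold genes, against 4% without the trend, and 0.020% of the unchanged genes. Of 200 simulated lists of 20 unchanged genes, drawn with an SD of 0.5 between genes, 7% stood apart, and of such lists shifted by 0.4 on the log2 scale, 87.5% did. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.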

Results

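The data were gene expression values of PC3 cells after transfection with a control siRNA or with an siRNA against POH1, with 1 library per group. The design asks which transcripts differ when POH1 is targeted. In the control library 14902 genes reached 1 TPM, and in the POH1 siRNA library 15033 did. Across the 15008 genes with a mean of 1 TPM or more, log2(TPM + 1) in the libraries had a Pearson correlation of 0.97 and a Spearman correlation of 0.96, which is across genes that are not independent replicates. Of these genes, 80.9% differed by under 1.5-fold. With 1 library per group, no value below has an error, and none of the differences can be set against a spread between replicates.

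The targeted gene, PSMD14 (ENSG00000115233), was at 50.9 TPM in the control library and 35.1 TPM in the POH1 siRNA library. The level that remained was 69.0% of the control, a log2 difference of -0.52. The direction goes with the label, but the size did not set PSMD14 apart from other genes. Among 3651 genes within 2-fold of its mean TPM, 8.93% had a difference as low or lower. Among the 588 of those with a GC content within 2.5 percentage points of its own, 23.5% did, and their median log2 difference was -0.17. The protein was not measured here.

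In all, 323 genes were at least 2-fold higher and 439 were at least 2-fold lower in the POH1 siRNA library. The median log2 difference of all genes was 0.12, so that values near 0 lie slightly below the middle of the distribution. Scaling to a median ratio of 1 lowers the differences by about 0.15 on the log2 scale, so list medians between 0 and 0.15 change sign under it; for this reason lists are placed among random lists from the same libraries. Of the 762 genes counted, 42.4% were higher. With that scaling, 219 were higher and 592 lower (27.0% higher), and after adjustment for GC content 426 were higher and 250 lower (63.0% higher).

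**Figure D1:**
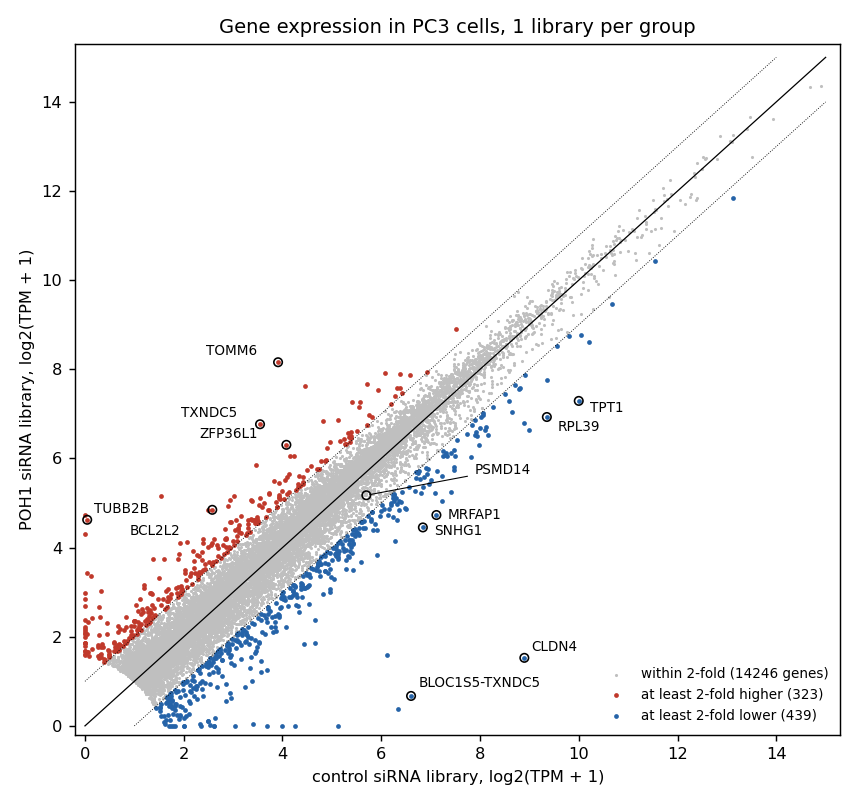
Expression of 15008 genes in the control siRNA library (horizontal axis) and the POH1 siRNA library (vertical axis), both as log2(TPM + 1), with the diagonal and dotted 2-fold lines. Red points are the 323 genes at least 2-fold higher and blue points the 439 at least 2-fold lower; circled genes are named in the text, and PSMD14 lies inside the 2-fold lines.

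The gene with the largest difference was CLDN4, which encodes the tight junction protein claudin 4. It was at 476 TPM in the control library and 1.88 TPM in the POH1 siRNA library, a 253-fold lower value. Of other claudins, CLDN3, chosen after its values were seen, was at 52.1 and 58.8 TPM, and CLDN7 at 82.1 and 105 TPM. Of 10 measured claudin genes, CLDN4 included, 2 were at least 1.5-fold lower and 0 were 1.5-fold higher, so CLDN4 was not the only lower one. TPT1, which encodes the abundant translationally controlled tumour protein, was 6.57-fold lower (1023 against 156 TPM). RPL39, a ribosomal protein gene, was 5.40-fold lower (653 against 121 TPM), and the snoRNA host gene SNHG1 was 5.45-fold lower (114 against 20.9 TPM). Adding the 15 named TPT1 pseudogenes, or the 20 named RPL39 pseudogenes, left the log2 differences at -2.70 and -2.40. BLOC1S5-TXNDC5, MICOS10-NBL1, PEDS1-UBE2V1 and RPS10-NUDT3, given further below, had the largest differences below the control after CLDN4. The remaining genes among the 12 lowest were MAIP1 (24.3 against 2.64 TPM), COX7B2 (20.6 against 2.56 TPM), AGAP5 (11.9 against 1.38 TPM) and MRFAP1 (138 against 25.6 TPM). AGAP5 belongs to a family of near-identical copies, and its value is uncertain for that reason.

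The gene with the largest difference in the other direction was TUBB2B, a beta-tubulin gene, at 0.0315 TPM in the control library and 23.7 TPM in the POH1 siRNA library. Its close paralogue TUBB2A, chosen after its values were seen, was at 35.9 and 49.1 TPM, and values of such copies are uncertain. TUBB2B also overlaps PSMG4 on the opposite strand, which was at 41.5 and 38.5 TPM, so its value is uncertain where reads were not assigned by strand. ZFP36L1, which encodes an RNA-binding protein that promotes decay of AU-rich messenger RNAs, was 4.91-fold higher (15.9 against 78.1 TPM). BCL2L2, which encodes the survival protein BCL-W, was 5.59-fold higher (4.97 against 27.8 TPM). The secreted protein gene TSKU was 5.62-fold higher (10.1 against 56.6 TPM), the trans-Golgi gene TGOLN2 6.02-fold higher (4.61 against 27.8 TPM), and the kinetochore gene CENPH 5.83-fold higher (2.80 against 16.3 TPM). SLC6A6, the taurine transporter, was at 6.67 and 32.5 TPM, CYTH3 at 7.09 and 34.4 TPM, and ELFN2 at 1.59 and 12.4 TPM.

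Of the 24 genes named by size, 11 (45.8%) share same-strand exon sequence with another measured gene, against 9.16% of all genes with a mean of 5 TPM or more and 14.9% of the 476 such genes that differed by at least 2-fold. The read-through gene BLOC1S5-TXNDC5 was at 96.3 TPM in the control library and 0.593 TPM in the POH1 siRNA library, while TXNDC5, a protein disulfide isomerase family gene, went the other way, from 10.7 to 108 TPM. The sum over these 2 genes was 107 and 109 TPM. RPL36A-HNRNPH2 was at 21.004 and 196 TPM, and its sum with RPL36A and HNRNPH2 was 1281 and 893 TPM. MICOS10-NBL1 (34.1 TPM) and RPS10-NUDT3 (11.95 TPM) were listed at 0 in the POH1 siRNA library, and their sums with the overlapping genes differed by -0.64 and 0.39 on the log2 scale. TOMM6, which encodes a subunit of the mitochondrial import pore, was at 14.04 and 285 TPM, and its sum with the overlapping gene still differed by 1.80 on the log2 scale. PEDS1-UBE2V1 was at 68.0 and 2.02 TPM, with a difference of -1.39 for the sum. For MAIP1, TPT1, SNHG1 and BCL2L2, which also share exons, the sums differed by -2.09, -2.70, -2.32 and 1.75.

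The log2 difference increased with the GC content of the transcripts. Across 10114 genes with a mean of 5 TPM or more, the Spearman correlation was 0.46, across genes that are not independent replicates. The median log2 difference was -0.24 in the 446 genes with up to 40% GC, -0.20 in the 1756 genes above 40% and up to 45%, 0.15 in the 1873 genes above 50% and up to 55%, and 0.33 in the 416 genes above 65%. Genes at least 2-fold lower made up 8.30% of the first of these groups and 0.240% of the last. The correlation with transcript length was 0.10. For the gene lists below that stood apart, the percentile among random lists also matched on GC content is given as well.

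**Figure D2:**
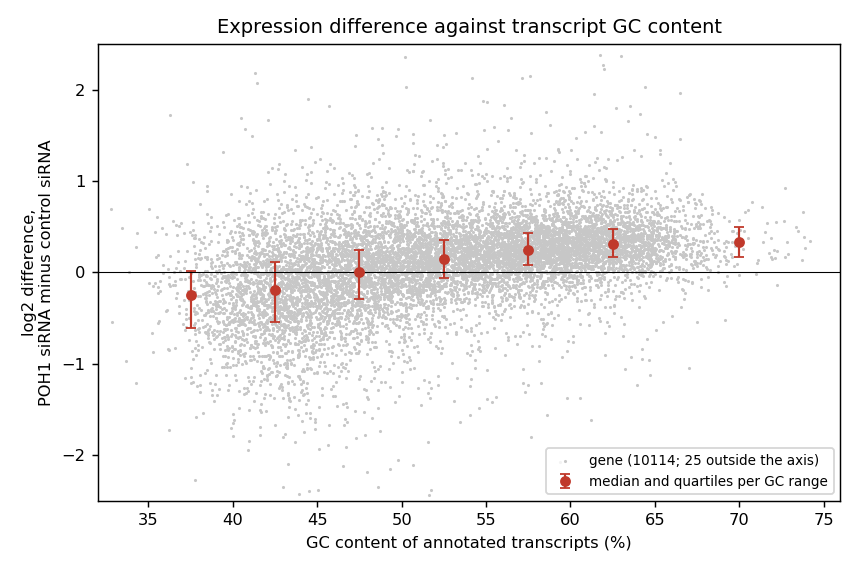
Log2 difference between the POH1 siRNA and control siRNA libraries (vertical axis) against the GC content of annotated transcripts in percent (horizontal axis) for 10114 genes with a mean of 5 TPM or more, as grey points. Red points and bars are the median and quartiles in 7 GC ranges, from -0.24 in the lowest to 0.33 in the highest; 25 genes lie outside the axes.

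Of 28 gene lists, 3 stood apart as higher and 6 as lower than random lists matched on mean TPM. The GC-matched random lists used 5 classes of mean TPM in place of 10. With 5 classes and no GC matching, 8 of these 9 stood apart, and with GC matching 2 did, both as higher. None of the 19 other lists stood apart with GC matching, where their percentiles ran from 11.01 to 95.1 (median GC 45.2% to 56.4%).

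Targets of NF-kB, most of them cytokines and feedback inhibitors, were higher as a group in the POH1 siRNA library. The median log2 difference of the 19 measured genes was 0.41, or 0.29 above the median of all genes. Of the 19 genes, 6 were at least 1.5-fold higher, none was 1.5-fold lower and 13 lay within 1.5-fold, on the log2(TPM + 1) scale used for these counts throughout. CXCL3, a neutrophil chemokine, was 1.81-fold higher (180 against 326 TPM), CXCL2 1.62-fold higher (106 against 171 TPM), TNFAIP3, which encodes the feedback inhibitor A20, 1.69-fold higher (20.7 against 34.9 TPM) and IER3 1.55-fold higher (1244 against 1929 TPM). TNFAIP3 and IER3 overlap genes on the opposite strand, so their values are uncertain where reads were not assigned by strand. The list median was at percentile 99.95 of random lists matched on mean TPM and 99.96 of those also matched on GC content (median GC 50.9%).

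Immediate early genes and genes of MAPK feedback had a median log2 difference of 0.39 over 19 genes, of which 4 were at least 1.5-fold higher and none 1.5-fold lower. KLF6 was 2.46-fold higher (7.41 against 18.2 TPM), EGR1 was at 1.39 and 3.50 TPM, MYC at 4.69 and 9.38 TPM, and NR4A1 at 13.1 and 24.6 TPM. The percentile was 99.7 with lists matched on mean TPM and 98.1 with lists also matched on GC content, but 97.4, no longer apart, when the differences were GC-adjusted too. The list of TGF-beta and YAP targets also holds ligands, receptors and other components of TGF-beta signalling, so it is not a measure of targets alone. Its median was 0.31 over 20 genes, with 3 at least 1.5-fold higher and none lower. The 3 were CCN2 (12.8 against 21.5 TPM) and the receptor genes TGFBR2 (13.3 against 21.9 TPM) and TGFBR1 (0.637 against 1.68 TPM). SKI, at 24.2 and 35.5 TPM, lay within 1.5-fold. This list was at percentile 97.7, at 96.9 with 5 classes of mean TPM and at 96.8 with lists also matched on GC content. It did not stand apart with a pseudocount of 0.1 (percentile 96.1), without a filter (96.8), or under any of the 3 other scalings (96.9 to 97.1).

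The proteasome genes did not move as a block. In the 20S core particle, 6 of 14 subunits were at least 1.5-fold lower and 8 lay within 1.5-fold (median -0.01, percentile 7). All 6 were alpha subunits: PSMA1 was 2.32-fold lower (123 against 52.97 TPM), PSMA6 2.09-fold lower (268 against 128 TPM), PSMA4 1.75-fold lower (51.0 against 29.1 TPM) and PSMA2 1.64-fold lower (132 against 80.3 TPM). The median of the 7 alpha subunits was -0.71 and that of the 7 beta subunits 0.05. This split was not fixed in advance. The fixed list, all 14 subunits, did not stand apart (percentile 76.3 with GC-matched lists). The alpha subunit genes had a median GC content of 43.2% and the beta subunit genes 48.7%. After GC adjustment the difference between the medians went from -0.76 to -0.42, and 2 alpha subunits, PSMA1 (-0.92) and PSMA6 (-0.77), were still at least 1.5-fold lower. PSMA1 and PSMA6 each share exons with another gene, and the log2 differences of the sums with it were -1.19 and -1.05. In the 19S regulatory particle without PSMD14, 1 of 18 subunits was higher (PSMD11, 52.997 against 93.4 TPM), 1 was lower (PSMC1, 114 against 75.6 TPM) and 16 lay within 1.5-fold (median 0.04, percentile 10.2); PSMD3 was at 201 and 280 TPM and PSMD1 at 165 and 119 TPM. NFE2L1, which encodes the transcription factor that induces proteasome genes when proteasome activity is low, was at 130 and 158 TPM.

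Assembly factors and regulators of the proteasome, listed with the immunoproteasome subunits PSMB8, PSMB9 and PSMB10, had a median of -0.11 over 17 genes. Of these, 4 were lower and none was higher. PSMG1, an assembly chaperone, was 2.77-fold lower (55.9 against 20.1 TPM), the maturation factor POMP 2.42-fold lower (32.4 against 13.4 TPM), PSME3 1.71-fold lower (39.6 against 23.2 TPM) and PSMG2 1.55-fold lower (35.9 against 23.2 TPM). The percentile of this list was 1.28, and 4.59 with lists also matched on GC content, but 0.195 when the differences were GC-adjusted too. Another list held genes of the PSMD14 family and deubiquitinases bound to the proteasome. Of its 12 genes, 2 were lower, USP14 (26.5 against 13.1 TPM) and EIF3H (232 against 142 TPM). PRPF8 was at 96.0 and 130 TPM and BRCC3 at 6.19 and 8.12 TPM (list median -0.10, percentile 6.40). The family members, EIF3H and PRPF8 among them, need not be active deubiquitinases. Ubiquitin and autophagy genes had a median of 0.14 over 21 genes at percentile 46.4, with 2 higher and 4 lower. The 4 lower genes were GABARAPL1 (39.7 against 15.9 TPM), RPS27A (757 against 368 TPM), USP14 and MAP1LC3B (43.6 against 22.4 TPM).

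The stress pathways that respond to misfolded proteins were not higher as groups. Cytosolic heat shock genes had a median of -0.13 over 15 genes, with 1 higher and 5 lower (percentile 1.91, and 15.9 with GC-matched lists; median GC 46.8%). This list did not stand apart with a pseudocount of 5 (percentile 4.25), median scaling (3.11) or trimmed mean scaling (2.80), and its median was 0.026 without a filter (14.8) and -0.35 with a filter at 5 TPM (0.030). HSP90AA1 was 2.34-fold lower (439 against 187 TPM), HSPE1 was at 140 and 71.4 TPM and DNAJA1 at 106 and 55.5 TPM. DNAJB4, in contrast, was at 0.770 and 2.23 TPM. HSPE1 and HSPD1, both among the 5 lower genes, encode mitochondrial chaperones, although the list is named for the cytosol. Log2 differences were above 0 for 7 of the 15 genes and below 0 for 8. HSPA1A (232 and 315 TPM), HSPA1B (211 and 287 TPM) and DNAJB1 (227 and 295 TPM), chosen after their values were seen, were above the control but within 1.5-fold. Genes of the integrated stress response had a median of 0.24 over 17 genes at percentile 84.6, with 2 higher and 2 lower. DDIT3, which encodes CHOP, was 1.65-fold higher (38.1 against 63.0 TPM) and SESN2 was 1.56-fold higher (13.4 against 20.9 TPM). ASNS was 2.31-fold lower (26.4 against 11.4 TPM), TRIB3 was 1.59-fold lower (100 against 63.1 TPM), and ATF4 was at 451 and 540 TPM. All 19 genes of the endoplasmic reticulum unfolded protein response lay within 1.5-fold on the log2(TPM + 1) scale (median 0.11, percentile 33.3), with SEL1L (5.49 and 8.44 TPM), DNAJB9 (3.36 and 5.25 TPM), HERPUD1 (107 and 75.9 TPM) and HYOU1 (110 and 147 TPM) farthest apart. Oxidative stress genes and metallothioneins had a median of 0.15 over 18 genes at percentile 54.1; AKR1C1 was lower (11.4 against 4.61 TPM), MT1F was higher (6.57 against 10.4 TPM), and TXN (414 and 282 TPM) and OSGIN1 (30.5 and 43.9 TPM) lay within 1.5-fold.

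Among cell death genes, BCL2L11, which encodes the BH3-only protein BIM, was 3.44-fold higher (1.48 against 5.08 TPM), and CASP9, the initiator caspase of the mitochondrial pathway, 2.19-fold higher (10.3 against 22.5 TPM). BCL2L11 overlaps the long noncoding RNA gene MIR4435-2HG on the opposite strand, so its value is uncertain. BID was lower (53.5 against 33.8 TPM). In all, 4 of the 18 proapoptotic genes were higher, 1 was lower and 13 lay within 1.5-fold (median 0.27, percentile 91.6). Of 10 antiapoptotic genes, 1 was higher, BCL2L2, and 1 was lower, BCL2A1 (23.1 against 12.9 TPM); TNFAIP8 was at 6.33 and 3.96 TPM and BIRC3 at 3.41 and 2.48 TPM (median -0.10, percentile 8.85).

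Mitotic genes had a median of -0.13 over 25 genes, with none higher and 5 lower. CDC25C, the phosphatase that activates CDK1, was 2.38-fold lower (19.6 against 8.24 TPM), CCNB2 2.19-fold lower (45.8 against 20.9 TPM), TOP2A 2.03-fold lower (18.9 against 9.31 TPM) and PTTG1 1.61-fold lower (326 against 202 TPM). The percentile was 0.395, and 21.7 with GC-matched lists (median GC 45.4%). Genes of DNA replication and E2F targets had a median of 0.07 over 30 genes at percentile 17.7, with none higher and 2 lower, RRM1 (52.6 against 25.9 TPM) and POLE2 (19.3 against 12.3 TPM); CCNE2 (0.838 and 1.72 TPM) and CDC6 (20.6 and 14.3 TPM) lay within 1.5-fold, and E2F1 was at 48.1 and 59.4 TPM. DNA repair genes had a median of -0.23 over 22 genes, with none higher and 5 lower. The helicase gene BLM was 4.11-fold lower (6.81 against 1.65 TPM), ATM was at 3.81 and 0.856 TPM, RAD51C at 29.3 and 11.4 TPM and MSH6 at 12.6 and 6.61 TPM (percentile 0.260, 3.99 with GC-matched lists, and 1.95 when the differences were GC-adjusted too; median GC 44.6%). Cell cycle inhibitors and p53 targets had a median of 0.19 over 18 genes at percentile 72.6, with 2 higher, GDF15 (51.9 against 84.6 TPM) and CDKN1C (7.46 against 11.8 TPM), and 1 lower, SESN1 (1.64 against 0.661 TPM). CDKN1B was at 6.91 and 10.5 TPM and CDKN1A at 105 and 147 TPM.

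Mitochondrially encoded messenger RNAs took 13.0% of the TPM in the control library and 9.98% in the POH1 siRNA library. Their median log2 difference was -0.49 over 13 genes, with 3 at least 1.5-fold lower: MT-ATP8 (3002 against 1382 TPM), MT-ND6 (2761 against 1570 TPM) and MT-ND4 (11652 against 6942 TPM). MT-ND2, at 5298 and 3544 TPM, lay just within that limit. The list was at percentile 0.010, and 6.25 with GC-matched lists (median GC 44.3%). Nuclear genes of oxidative phosphorylation had a median of -0.07 over 23 genes, with 1 higher and 6 lower, among them ATP5PB (244 against 89.1 TPM), NDUFS1 (44.2 against 19.6 TPM), UQCRB (74.9 against 33.9 TPM) and NDUFB3 (181 against 103 TPM); the percentile was 0.745, and 19.2 with GC-matched lists. Cytosolic ribosomal protein genes had a median of 0.03 over 38 genes at percentile 2.94. Of these, 3 were lower, RPL7 (1174 against 391 TPM), RPS24 (8938 against 3648 TPM) and RPL30 (3888 against 2216 TPM), 1 was higher, RPL23 (434 against 851 TPM), and 34 lay within 1.5-fold. The list does not hold all ribosomal protein genes: of 48 measured RPL genes, paralogues included, 11 were at least 1.5-fold lower and 1 was higher (median -0.09, percentile 0.020, and 3.12 with GC-matched lists). Of 31 RPS genes, without the S6 kinases that share the prefix, 5 were lower and none was higher (median -0.12, percentile 0.075, and 0.930 with GC-matched lists). These symbol groups, which were not fixed in advance, include RPL39 and RPS27A. Ribosomal protein genes have many processed pseudogenes, so single values are uncertain.

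**Figure D3:**
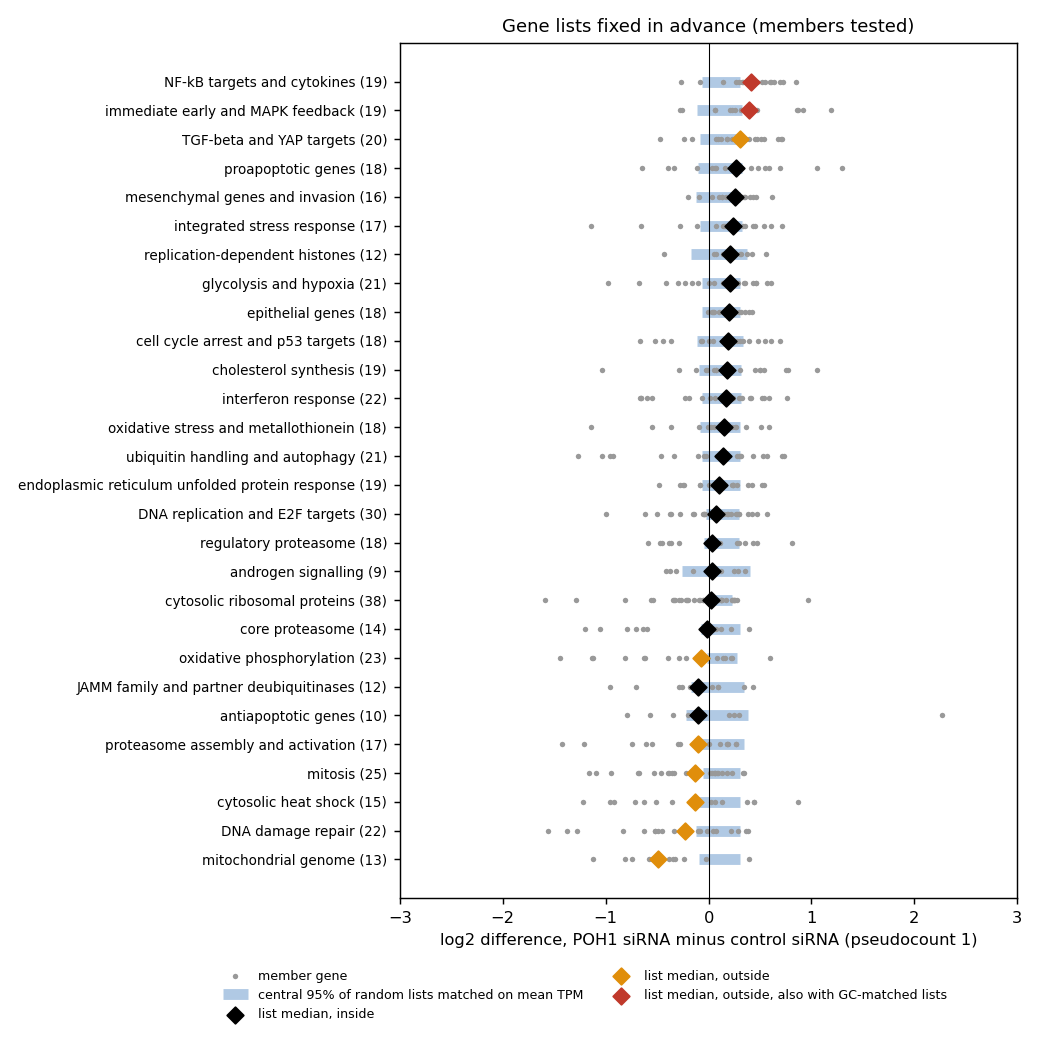
Log2 difference, POH1 siRNA less control siRNA with a pseudocount of 1 (horizontal axis), for the members (grey points) and medians (diamonds) of 28 gene lists, with the number of measured members after each name. Blue bars span the central 95% of medians of random lists matched on mean TPM; 9 medians lie outside their bar (orange or red), and the 2 red ones, NF-kB targets and immediate early genes, also stand apart from GC-matched lists, the second not after GC adjustment. The value of CLDN4 lies outside the axis.

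The other lists did not stand apart from random lists matched on mean TPM. Interferon-stimulated genes had a median of 0.17 over 22 genes at percentile 61.3, with 2 higher and 4 lower: IRF7 was 1.71-fold higher (60.5 against 104 TPM), while IFI6 (461 against 291 TPM), IFIT2 (8.38 against 4.94 TPM) and IFI44 (26.1 against 16.2 TPM) were lower. Cholesterol synthesis genes had a median of 0.18 over 19 genes at percentile 67.0 (98.9 with GC adjustment and GC-matched lists), with 3 higher, among them DHCR7 (84.6 against 177 TPM) and SQLE (17.0 against 29.2 TPM), and 1 lower, SC5D (6.93 against 2.87 TPM). Glycolytic and hypoxia genes had a median of 0.20 over 21 genes at percentile 80.1, with LDHA, which encodes lactate dehydrogenase A, 1.97-fold lower (1563 against 792 TPM), NDRG1 lower (244 against 152 TPM), PFKFB3 higher (7.18 against 11.4 TPM) and VEGFA at 126 and 187 TPM. Epithelial genes had a median of 0.20 over 18 genes at percentile 75.2, and apart from CLDN4 all lay within 1.5-fold, with OCLN (6.92 and 9.63 TPM), TJP3 (22.9 and 30.3 TPM) and CLDN7 next in size. Mesenchymal and invasion genes had a median of 0.26 over 16 genes at percentile 93.0, with ZEB1 higher (0.944 against 1.98 TPM) and ITGB3 (0.906 and 1.63 TPM) and MMP14 (161 and 218 TPM) within 1.5-fold. All 9 measured genes of androgen signalling lay within 1.5-fold (median 0.03, percentile 28.8), including STEAP1 (23.2 and 17.2 TPM), TMPRSS2 (9.89 and 12.9 TPM) and STEAP4 (11.3 and 8.90 TPM). All 12 measured replication-dependent histone genes, whose messages mostly lack a poly(A) tail, lay within 1.5-fold (median 0.21, percentile 74.3), including H2BC5 (26.5 and 39.6 TPM), H2BC9 (1.95 and 1.19 TPM), H2AC6 (9.30 and 12.8 TPM) and H2BC4 (36.7 and 47.9 TPM).

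Marker lists of other cell types had 2 members each with a mean of 1 TPM or more and were not placed among random lists. The leukocyte list held LCP1 (179 and 103 TPM) and CD14 (1.59 and 2.11 TPM), and the fibroblast list COL1A1 (30.9 and 47.8 TPM) and ACTA2 (5.87 and 4.43 TPM). The endothelial list held PECAM1 (4.90 and 3.88 TPM) and ESAM (6.73 and 6.74 TPM), and the neuroendocrine list ENO2 (62.2 and 84.0 TPM) and SYP (1.10 and 1.07 TPM).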

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

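No paired analysis was possible because each group held 1 library, and for the same reason no replicate could be left out. The alternatives for GC content, 5 classes of mean TPM, exon sharing and protein-coding genes were chosen after the data were seen. PSMD14 stayed lower in all settings run, with log2 differences from -0.67 (median scaling) to -0.24 (GC-adjusted), and the Pearson correlation between the libraries ranged from 0.956 to 0.983. All 144 values of the 24 named genes over 6 alternatives kept their direction and a 2-fold size. Of these values, 128 moved by under 1.5-fold. The genes were chosen for the largest differences, so this outcome was largely fixed in advance. Sums over overlapping genes were not among the 6 alternatives, and for 5 of the 24 genes the same-strand sum differed by under 2-fold. The numbers of 2-fold genes depended on the pseudocount and the filter: 649 higher and 672 lower with a pseudocount of 0.1, 100 and 190 with a pseudocount of 5, and 184 and 292 with a filter at 5 TPM, where fewer genes were counted. Of the 439 lower genes, 234 were also lower after GC adjustment, which gave 250 in all. Without the genes that share exons, 254 were higher and 360 lower, and among protein-coding genes 232 and 309. The unknown depth keeps low genes from being separated from counting error. The NF-kB target list stood apart in every setting (percentiles 99.92 to 100). The TGF-beta and YAP list no longer did with a pseudocount of 0.1 (median 0.31), without a filter (0.31), with median (0.16) or trimmed mean scaling (0.18), without the most abundant genes (0.24), with 5 classes of mean TPM (0.31), with GC-matched lists (0.31) or with GC adjustment (0.24). The heat shock list no longer did with a pseudocount of 5 (-0.063), without a filter (0.026), with median (-0.24) or trimmed mean scaling (-0.22), with GC-matched lists (-0.13) or with GC adjustment (-0.077), whereas with a filter at 5 TPM its median was -0.35 at percentile 0.030. With GC-matched lists, 2 lists stood apart, and the lists for proteasome assembly (median -0.11), mitosis (-0.13), oxidative phosphorylation (-0.074), the mitochondrial genome (-0.49) and DNA repair (-0.23) no longer did. The ribosomal protein list did without a filter (percentile 1.46) and with 5 classes of mean TPM (1.52). With GC adjustment as well as matching, 4 lists did, NF-kB targets, proteasome assembly, DNA repair and cholesterol synthesis (0.34); mitosis (0.053), oxidative phosphorylation (0.0031), the mitochondrial genome (-0.21) and immediate early genes (0.30, percentile 97.4) did not. Apart from fewer or other genes being counted, and the GC trend being removed by construction, the cause was not tested.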

Other observations

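Some single genes outside the lists differed from related genes. B2M, the light chain of MHC class I, was 3.28-fold higher in the POH1 siRNA library (46.3 against 152 TPM), against the GC trend, as its transcripts have 40.5% GC; its GC-adjusted log2 difference was 2.09. HLA-C was 3.93-fold higher (51.6 against 203 TPM), whereas HLA-B was at 159 and 151 TPM and HLA-E at 157 and 167 TPM. TAP1 was at 46.2 and 57.9 TPM and TAP2 at 72.1 and 50.1 TPM. IFITM1 was 3.59-fold higher (66.8 against 240.1 TPM), while IFITM2 was at 312 and 354 TPM and IFITM3 at 933 and 970.3 TPM. HLA and IFITM genes are closely related copies, so single values are uncertain. These genes were chosen after their values were seen, and no test was made.

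The tests of overlapping genes and of libraries per group, and the comparison with 5 classes of mean TPM, were chosen after the results were seen, and the GC settings were added after the data were seen, with the limits for their tests written before those results. In the first pattern, genes with AT-rich transcripts were lower in the POH1 siRNA library. A technical explanation is a difference in GC bias between the 2 libraries, from amplification or fragmentation, for example. After removal of the GC trend, the number of genes at least 2-fold lower was 56.9% of the number before. The difference between 20S alpha and beta subunits, a split not fixed in advance, was 54.6% of its size before. Both values lie between the limits of 50% and 75% set for and against GC as the cause, and the trend cannot be told apart from an effect of the siRNA on AT-rich transcripts, since each group held 1 library. Among 140 families of genes with a shared symbol prefix, 23 stood apart from random lists matched on 5 classes of mean TPM. With lists matched on these classes and GC content 9 did, a decrease of 60.9%, where 7 would by chance. This goes with the GC trend as a source of many of the family differences. It leaves some far out, such as TSPAN genes (median -0.34, percentile 0.020 with GC matching) and INTS genes (median 0.42, percentile 99.94). Of 15 TSPAN genes, 6 were at least 1.5-fold lower and 0 higher. The INTS genes were split, with 2 of 16 at least 1.5-fold higher and 3 lower. After GC adjustment the medians were -0.20 for TSPAN and 0.28 for INTS, against 0.15 for all genes.

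In the second pattern, the largest differences were often at loci with overlapping genes, where reads divided differently between overlapping genes are a technical explanation. For 12 named genes, CLDN4, RPL39 and ZFP36L1 among them, GENCODE release 29 has no overlapping gene with a mean of 1 TPM or more on either strand. Overlap with such a gene does not account for these 12. The annotation behind the TPM values is not known, so overlaps that only it holds were not examined. Reads shared with distant copies were not excluded either. For 6 of the 12 others (TUBB2B, BCL2L2, PEDS1-UBE2V1, MAIP1, TPT1 and SNHG1), the overlapping genes moved little the other way. The share was at most 23.6% of the change in TPM, and at most 21.3% in TPM times transcript length. This was under a limit of 25% set after the values were seen, and PEDS1-UBE2V1 (23.6%) lay close to it. A plain exchange of reads does not account for these 6, but one combined with changes in the overlapping genes is not excluded. For the other 6, a redivision of reads cannot be told apart from a change in the transcripts, as the share reached 25%. In TPM and in TPM times transcript length it was 18.4% and 90.9% for TOMM6, and 27.0% and 38.7% for MICOS10-NBL1. It was 98.3% and 229% for TXNDC5, and 102% and 43.9% for BLOC1S5-TXNDC5. For RPL36A-HNRNPH2 and RPS10-NUDT3 the overlapping genes moved by more than the named gene. No biological explanation of these single-gene differences was tested.

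In the third pattern, NF-kB targets were higher as a group. The tables argue against the GC trend as the cause, since the list was at percentile 99.96 of random lists matched on GC content as well as mean TPM. A hypothesis, not tested here, is that targeting POH1 raises NF-kB target transcripts, for which replicate libraries and another siRNA would be needed. A difference between the cultures or libraries that is unrelated to the siRNA cannot be told apart from it, because there was 1 library per group, and genes of this list are often regulated together, which random lists do not reproduce. The small difference in PSMD14 leaves open how strongly the target was reduced in these cells.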
